A study of Homo sapiens with 3 samples.

How the data were processed

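Gene expression was measured in HCT116 cells infected with an adenoviral vector for LacZ, DGKG-KD or DGKG-CA, with 1 array for each. Per the labels' protocols, total RNA was extracted with TRIZOL 24 h after infection, and 100 ng was labelled with Cy3 using an Agilent 1-colour Low Input Quick Amp kit. The authors deposited, for each array, the spot intensity table of Agilent Feature Extraction (version 10.7, per the submitters' processing notes). Per the file headers, the processed signal is a linear intensity that was background-subtracted and spatially detrended within the array by the 1-colour protocol, with no scaling between arrays, and probe positions refer to hg19. The value table of the series holds the same processed intensity for each spot, within 0.5% of the scanner files on all spots, so its scale is linear, it is not centred and it holds signals with no direction. Its column medians over gene spots were 76.5 (LacZ), 74.6 (DGKG-KD) and 72.4 (DGKG-CA). All 3 arrays came from 1 slide with 1 scan time, so slide and scan did not differ between the groups.

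From these deposited intensities, log2 of the processed signal was taken and each array's 75th percentile over gene spots (746 for LacZ, 701 for DGKG-KD and 664 for DGKG-CA) was subtracted. Control spots were left out, as were spots flagged as outliers (277, 298 and 379 on the 3 arrays), and 0 spots were saturated. Spots of a probe were averaged. A gene was represented by the probe with the highest mean log2 signal over the 3 arrays, and it counted as measured in a comparison when that probe was well above background, by the flag in the files, on both arrays. Where a gene had a second such probe, the log2 ratios of the 2 probes correlated across genes at 0.422 for DGKG-KD against LacZ (3200 genes), 0.509 for DGKG-CA against LacZ (3253 genes) and 0.217 for DGKG-CA against DGKG-KD (3203 genes). Of genes whose brighter probe was at least 1.5-fold apart, the second probe lay on the same side in 30 of 39, 64 of 70 and 4 of 5, and passed 1.5-fold itself in 9, 22 and 1. For genes with a probe well above background on 1 array of a pair and none on the other, a lower bound is given as the bright array's level over the higher of the dim array's own level and its lowest signal well above background.

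Probe accessions were matched without version numbers to a RefSeq gene table (GRCh38.p14, used for names only), which named 24823 probes. A further 1191 probes were named by symbol and 472 by an older symbol, and 15919 probes had no symbol. Coordinates are those of the probe in the files and their build, and no gene model of hg19 was used here.

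There is 1 array per group, so no model was fitted and no test was run. Genes at least 2-fold or 1.5-fold apart were counted. The technical error came from probes with 10 spots, whose SD of log2 signal within an array was 0.172 to 0.185 for signals under 100, 0.0787 to 0.0839 for 100 to 1000 and 0.0528 to 0.0532 over 1000. Before the data were examined, 20 gene lists with 567 distinct genes were fixed. They covered the DGK family, phosphatidic acid and glycerolipid enzymes, the ERK pathway and immediate early genes, interferon-stimulated genes, NF-kB targets, p53 targets, S phase and E2F genes, G2 and M phase genes, the unfolded protein response and ATF4 targets, and heat shock genes. They also covered Wnt and beta-catenin targets, cholesterol synthesis and SREBP targets, SRF and YAP targets, hypoxia and glycolysis genes, epithelial genes, mesenchymal genes, leukocyte markers, ribosomal protein genes and common reference genes. The results of 1 further list are not reported here. For 2 of the list genes no probe was analysed here. SESN2, MYC, ACTB and PGK1 each stand in 2 lists. Each list is described by its median log2 ratio and by that median's percentile among 10000 random lists of the same size drawn from 20 bins of mean expression, as a description of these arrays. For the agreement of the ratios to the shared LacZ array, 100 simulations of unchanged arrays, with the noise taken from the DGKG-CA to DGKG-KD ratio, gave the values set beside the observed ones.

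The genes named were chosen by a rule fixed before the data were examined. Per comparison it took the 10 highest and 10 lowest log2 ratios among genes with a symbol whose main probe was well above background and not an outlier or saturated on both arrays, and whose other measured probes lay on the same side of 0. Symbols that are accessions, LOC names, open reading frames or probe names were passed over. It added the 3 largest bounds per direction, up to 4 members per list with the largest ratio in size, DGKG, and the 5 genes with the largest distance per array and direction among genes with 1 array at least 2-fold from both others, those 2 being less than 1.5-fold apart. Genes named as highest or lowest without spots in patches were chosen after their values were seen.

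A patch was defined after the data were seen, as the spots that had, within 3 rows and 3 columns, at least 3 other spots at least 2-fold above both other arrays. Patches covered 295 spots of the LacZ array, 747 of the DGKG-KD array and 259 of the DGKG-CA array, and a gene is described as in a patch when a spot of its main probe lay in one. Alternatives fixed beforehand were normexp background correction (offset 50) on the mean and background signals, quantile normalization, scaling to the median, the values of the series table, the mean of a gene's detected probes, a minimum signal of 100 on the brighter array, no detection filter with signals below 5 set to 5, and leaving out genes with saturated or non-uniform spots. Leaving out patches and removing the trend with probe GC content and signal (10 by 10 bins) were added after seeing the data.

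The counting of genes was tested on simulated data for DGKG-KD against LacZ over 13417 genes. Of 50 genes each set to 1.5-fold, 2-fold, 3-fold and 4-fold, 23, 49, 50 and 50 passed 1.5-fold, and 1, 21, 50 and 50 passed 2-fold. Of 13217 unchanged genes 35 passed 1.5-fold and 0 passed 2-fold. The simulated noise was normal, scaled to the median absolute deviation of the DGKG-CA to DGKG-KD ratio, and held no patches or wide tails. On the real arrays 78 genes passed 1.5-fold and 17 passed 2-fold between DGKG-CA and DGKG-KD. The simulated counts of unchanged genes are therefore no error rate of these arrays. A simulated list of 30 genes shifted by 0.5 lay at percentile 100, and one without a shift at 67.3. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for normexp.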

Results

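HCT116, an established human colorectal carcinoma cell line, was infected with adenoviral vectors for LacZ, the bacterial beta-galactosidase gene used here as the control, or for DGKG-KD or DGKG-CA. DGKG is diacylglycerol kinase gamma, an enzyme that turns the lipid messenger diacylglycerol into phosphatidic acid. The labels do not spell out KD and CA, and the names are used here as given. Total RNA was taken 24 h after infection and hybridised to 1-colour Agilent arrays, with 1 array per vector and all 3 arrays on 1 slide. The arrays carried 42405 gene probes on 58717 spots, and 36452 spots were well above background on the LacZ array, 35466 on the DGKG-KD array and 36055 on the DGKG-CA array. Of 20042 named genes, 13755 were well above background on the LacZ array, 13554 on the DGKG-KD array and 13693 on the DGKG-CA array.

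With 1 array per vector there was no replicate, so no difference between vectors could be tested and no p-value is given. Replicate spots within an array gave an error, which bounds the error of a ratio from below. For probes printed 10 times, that spot-to-spot error (SD) of a log2 ratio between 2 arrays was at most 0.26 for signals under 100, 0.12 for signals of 100 to 1000 and 0.075 for signals over 1000. It leaves out the variation between cultures, labelling reactions and arrays, and the number of arrays limits the precision of every value. Ratios read by 2 probes of the same gene differed by more, with an SD of 0.26 for DGKG-KD against LacZ. That SD was 0.26 for DGKG-CA against LacZ and 0.22 for DGKG-CA against DGKG-KD, over signals of all levels. Ratios are log2 ratios of signals scaled to each array's 75th percentile, so higher and lower are relative to the other gene probes of the same arrays.

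DGKG itself was detected at a low signal on every array. DGKG was read by 1 probe at chromosome 3, 185865035 to 185865094 (hg19), printed on 2 spots. Its mean signal was 112 on the LacZ array, 128 on the DGKG-KD array and 105 on the DGKG-CA array. The log2 ratio to LacZ was 0.28 for DGKG-KD and 0.077 for DGKG-CA, and DGKG-CA minus DGKG-KD was -0.21. On the LacZ array alone the 2 spots read 94.0 and 133.6, a gap wider than any of the differences between array means. Whether the probe lies within the sequence carried by the vectors was not analysed here, so these values check nothing about the labels. Among the other diacylglycerol kinases, DGKA was read at log2 0.38 (DGKG-KD) and 0.35 (DGKG-CA) relative to LacZ. Over the 5 DGK family members well above background, the median was 0.11 for DGKG-KD (0.096 to 0.27 under the processing alternatives) and 0.077 for DGKG-CA (0.022 to 0.078), and no member was 1.5-fold apart.

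The first comparison asked how expression with DGKG-KD differed from that with the LacZ control. Genes of DNA replication were lower on the DGKG-KD array and genes of hypoxia and glycolysis were higher. All 35 genes of the S phase and E2F list were below the LacZ array, with a median log2 ratio of -0.53 (a ratio of 0.693, quartiles -0.62 and -0.39), and 12 were at least 1.5-fold lower. Of the 30 hypoxia and glycolysis genes, 28 were above the LacZ array, with a median of 0.47 (a ratio of 1.39, quartiles 0.22 and 0.62), and 11 were at least 1.5-fold higher. The p53 target list was also higher, with 30 of 31 members above 0, a median of 0.36 and 6 members at least 1.5-fold higher. These 3 medians lay outside those of all 10000 random lists matched on expression, which describes these arrays and is no test.

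In the S phase list, the transcription factor E2F1 stood at -0.99 (signal 567 on the LacZ array and 268 on the DGKG-KD array, chromosome 20, 32263989 to 32264048, hg19). GINS2, a subunit of the replicative helicase complex, stood at -0.90, the helicase subunit MCM2 at -0.76 and the uracil-DNA glycosylase UNG at -0.75. Among hypoxia genes, the glucose transporter SLC2A3 stood at 1.25, with signals of only 26.5 and 59.2, and carbonic anhydrase CA9 at 1.12. NDRG1, a gene induced by hypoxia, stood at 0.95 with a signal of 17688 on the LacZ array and 32049 on the DGKG-KD array, and ANKRD37 stood at 0.92. The largest p53 target ratios were those of BTG2, an antiproliferative gene, at 0.81, the kinases PLK3 at 0.65 and PLK2 at 0.63, and SESN1 at 0.63.

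The other lists were closer to the LacZ array. Interferon-stimulated genes had a median of 0.22 (percentile 100 among the random lists) with 20 of 27 above 0, OASL at 0.63, DDX60 at 0.57 and ISG20 at 0.55 among them, while HERC6 stood apart at -1.81. Mesenchymal genes had a median of 0.23 over only 5 measured members, led by vimentin (VIM) at 0.47, and leukocyte markers 0.23 over 9 members, led by CD68 at 0.41 (percentiles 96.7 and 98.0), with most members of both lists not well above background. The medians were 0.13 for targets of the unfolded protein response and ATF4 (27 genes, percentile 99.7, CHAC1 and ATF3 both at 0.50), 0.12 for ribosomal protein genes (43 genes, percentile 99.7, 0.015 after quantile normalization) and 0.10 for epithelial genes (20 genes, MUC2 at 0.46). They were 0.094 for phosphatidic acid and glycerolipid enzymes (28 genes, PLCH1 at 0.38), 0.066 for SRF and YAP targets (21 genes, ACTA2 at 0.80, ACTB at -0.36), 0.062 for cholesterol synthesis genes (32 genes, ACSS2 at 0.54) and 0.055 for common reference genes (15 genes, -0.019 after quantile normalization). Medians nearest to 0 were those of the ERK pathway and immediate early genes at 0.0091 (29 genes, FOSB at 0.53, SPRED2 at -0.47) and NF-kB targets at -0.021 (17 genes, NFKB1 at -0.43). Wnt and beta-catenin targets had a median of -0.030 (16 genes, MYB at -0.61), G2 and M phase genes -0.056 (37 genes, percentile 1.005, CDC25C at -0.39, MKI67 at -0.34) and heat shock genes -0.094 (18 genes, percentile 0.11, HSPH1 at -0.27, DNAJB4 at 0.49). Under the processing alternatives the medians of Wnt and beta-catenin targets (-0.076 to 0.065), NF-kB targets (-0.034 to 0.082), the ERK list (-0.027 to 0.023) and the common reference genes (-0.041 to 0.055) turned to the other side of 0. Without turning, the medians ran from 0.11 to 0.22 for interferon-stimulated genes, 0.089 to 0.23 for leukocyte markers, 0.18 to 0.37 for mesenchymal genes, 0.025 to 0.10 for epithelial genes, 0.038 to 0.097 for phosphatidic acid and glycerolipid enzymes, 0.018 to 0.066 for SRF and YAP targets, -0.098 to -0.054 for G2 and M phase genes and -0.16 to -0.094 for heat shock genes. Where members had other probes, the medians of those probes turned in some lists. They were -0.11 for epithelial genes (3 of 4 below 0), -0.23 for leukocyte markers (2 of 2) and -0.055 for cholesterol synthesis genes (3 of 5). In the other lists reported here they kept the side of the list median, which does not set each gene against its own main probe. In the DGK family they rest on DGKZ alone, at 0.20 by its other probe but -0.052 by its main probe. In the mesenchymal list they rest on 1 gene, at 1.06.

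**Figure D1:**
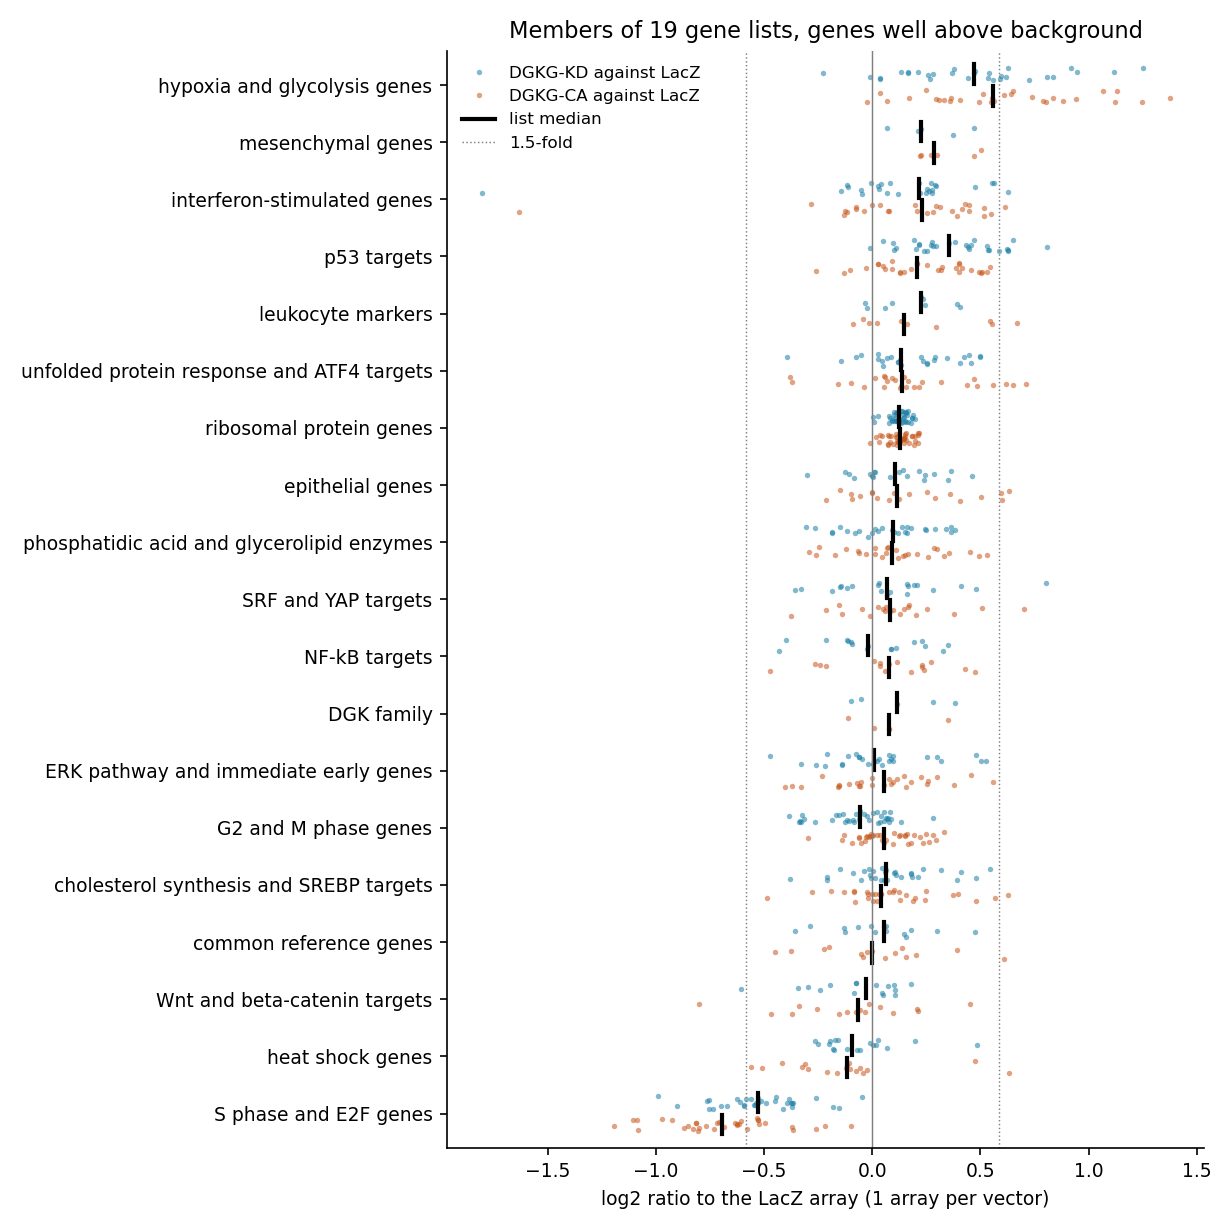
Log2 ratio to the LacZ array (horizontal axis) of each measured member of 19 gene lists (vertical axis), with DGKG-KD in blue and DGKG-CA in orange, 1 array per vector, black bars at the list medians and dotted lines at 1.5-fold. The S phase and E2F list lies furthest below 0 (medians -0.53 and -0.70) and the hypoxia and glycolysis list furthest above it (0.47 and 0.56), and the point far below the other interferon-stimulated genes is HERC6.

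Over all 13417 genes measured on both arrays, 25 were at least 2-fold higher with DGKG-KD and 4 at least 2-fold lower, and at 1.5-fold the counts were 187 higher and 124 lower, or 150 and 143 after quantile normalization. The 10 highest named genes, led by MFHAS1 at 3.88, DENND1B at 3.46 and SEC62 at 2.53, all had spots in patches, areas in which neighbouring spots were bright on 1 array alone, as did 3 of the 10 lowest, HOGA1 (-1.30), KAZN (-1.14) and POU2F2 (-0.98). Without spots in patches 12 genes were at least 2-fold higher and 2 at least 2-fold lower, and 164 and 119 passed 1.5-fold. Among genes that met the naming rule, which here leaves out E2F1 and GINS2, the highest ratios were then those of SLC2A3 (1.25), SOX30 (1.20), the lipid transporter ABCA12 (1.12), CA9 (1.12), the fucosyltransferase FUT3 (1.11) and the chemokine receptor CXCR4 (1.07, read by 10 spots, signals 192 and 378). On the LacZ array the signals were only 26.5 for SLC2A3, 44.4 for SOX30, 33.2 for ABCA12, 84.7 for CA9 and 26.5 for FUT3. The lowest under that rule were HERC6 (-1.81, signals 138 and 36.9), SH3RF2 (-1.09), the DNA repair gene RAD51AP1 (-0.96), DEF8 (-0.95), SLC68A1 (-0.94), RPRML (-0.93), PTPN21 (-0.86) and the histone genes H2BC7 (-0.92), H2AC13 (-0.86) and H2AC4 (-0.85). Of genes well above background on 1 array of the pair only, the largest bounds were also in patches, FLJ37201 at least 30.9-fold, KCNK12 at least 26.9-fold and ARHGAP25 at least 12.5-fold higher, and WFDC2 at least 12.6-fold and RIPPLY1 at least 2.75-fold lower. BNC2, at least 3.82-fold lower, was the exception.

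**Figure D2:**
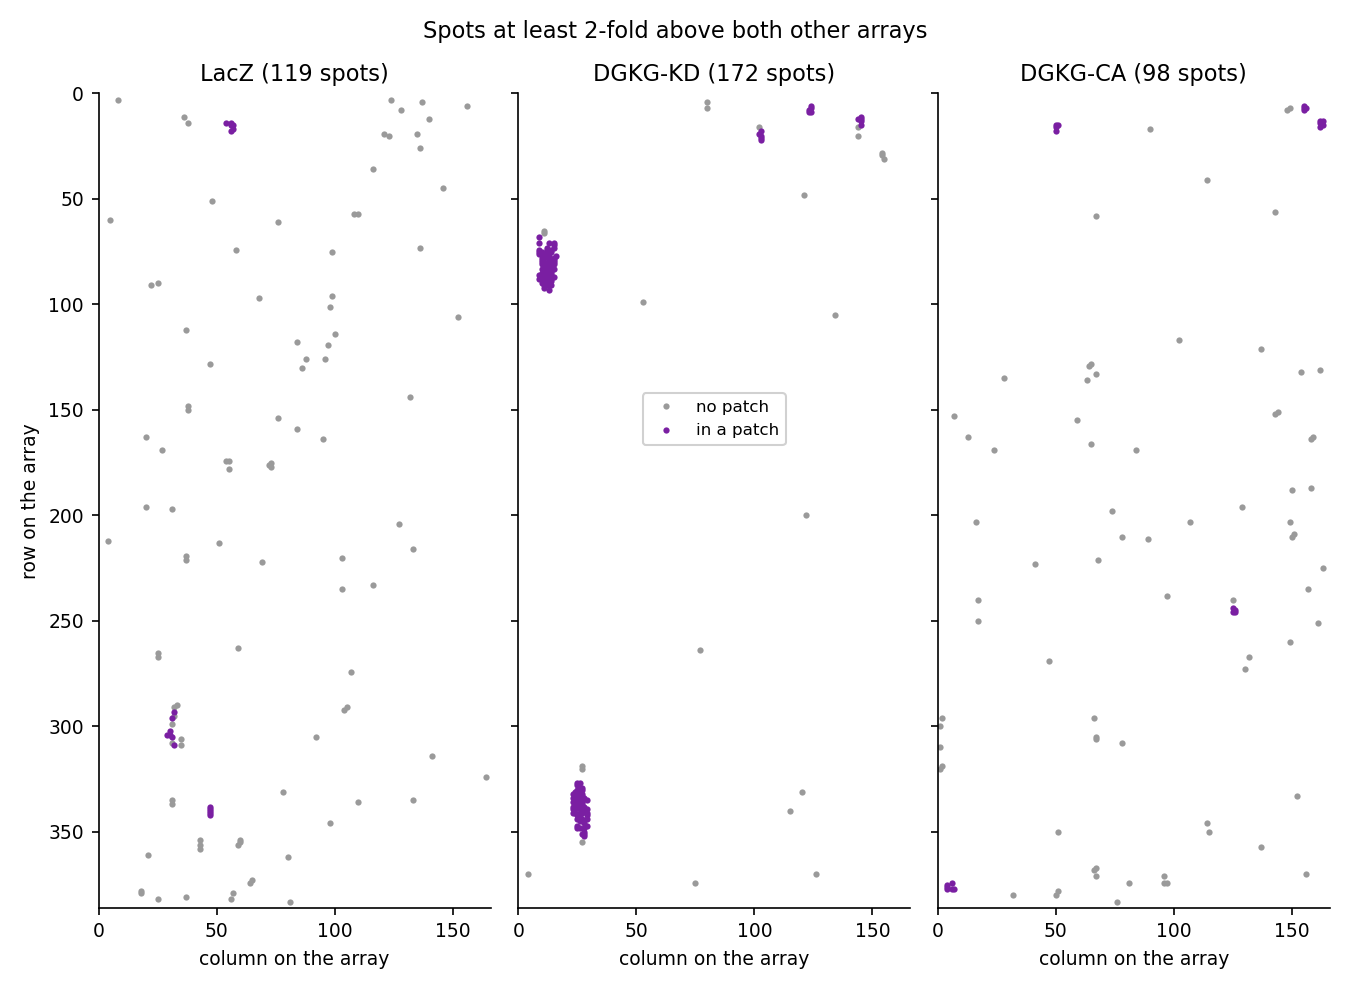
Position by row (vertical axis) and column (horizontal axis) of spots at least 2-fold above both other arrays, one panel per array, with spots in patches in purple. On the DGKG-KD array 149 of 172 such spots lie in patches, most of them in a pair of areas at rows 68 to 93 and rows 327 to 352, against 18 of 119 on the LacZ array and 23 of 98 on the DGKG-CA array.

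The next comparison set DGKG-CA against the same LacZ array. The S phase and hypoxia lists again stood furthest from 0. S phase and E2F genes had a median of -0.70 (a ratio of 0.617, quartiles -0.82 and -0.53), with all 34 measured members below the LacZ array, 23 at least 1.5-fold and 4 at least 2-fold lower. Hypoxia and glycolysis genes had a median of 0.56 (a ratio of 1.47, quartiles 0.34 and 0.83), with 29 of 30 members above it, 14 at least 1.5-fold and 5 at least 2-fold higher. The p53 target list had a median of 0.21, with 27 of 31 members above 0 and none 1.5-fold apart. All 3 medians lay outside those of all 10000 matched random lists.

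E2F1 stood at -1.19 (signal 221), the cyclin CCNE2 at -1.10, the replication initiation factor MCM10 at -1.09 and GINS2 at -1.08. On the other side, CA9 stood at 1.37, ANKRD37 at 1.25 (signals 4728 and 9974, chromosome 4, 186321293 to 186321352, hg19), the aldolase gene ALDOC at 1.13 (signals 2444 and 4769) and NDRG1 at 1.12. The p53 targets furthest from 0 were the cell cycle inhibitor CDKN1A at 0.54, BBC3 at 0.53, PLK3 at 0.51 and BTG2 at 0.50.

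Mesenchymal genes had a median of 0.28 over 6 measured members (TWIST1 at 0.50, VIM at 0.47), interferon-stimulated genes 0.23 with 19 of 28 above 0 (percentile 99.98, ISG20 at 0.62, OASL at 0.55, IFIT1 at 0.52, HERC6 at -1.63), and leukocyte markers 0.15 over 10 members (CSF1R at 0.67). Targets of the unfolded protein response and ATF4 had a median of 0.14 over 28 genes (percentile 99.4), with DDIT4 at 0.71, DDIT3 at 0.65 and ATF3 at 0.62. The medians were 0.13 for ribosomal protein genes (0.0034 after quantile normalization), 0.11 for epithelial genes (MUC2 at 0.63, TJP3 at 0.60, ELF3 at 0.59), 0.091 for phosphatidic acid and glycerolipid enzymes (PLCD1 at 0.53) and 0.084 for SRF and YAP targets (ACTA2 at 0.70). They were 0.077 for NF-kB targets (BCL3 at 0.48, NFKB1 at -0.47), 0.055 for the ERK pathway and immediate early genes (-0.039 after quantile normalization, DUSP1 at 0.56), 0.055 for G2 and M phase genes (NEK2 at 0.33) and 0.041 for cholesterol synthesis genes (STARD4 at 0.63). Below or at 0 were the common reference genes (median within 0.01 of 0, PGK1 at 0.61, TFRC at -0.45), Wnt and beta-catenin targets at -0.065 (MYB at -0.80) and heat shock genes at -0.12 (percentile 0.50, HSPH1 at -0.56, HSPA6 at 0.63). Under the processing alternatives the medians of Wnt and beta-catenin targets (-0.098 to 0.0091), the ERK list (-0.039 to 0.087) and the common reference genes (-0.019 to 0.024) turned. Without turning, the medians ran from 0.056 to 0.11 for phosphatidic acid and glycerolipid enzymes, 0.021 to 0.15 for leukocyte markers, 0.037 to 0.12 for epithelial genes, 0.037 to 0.18 for NF-kB targets, 0.020 to 0.098 for SRF and YAP targets and 0.028 to 0.075 for G2 and M phase genes. The medians of members' other probes turned to -0.070 for G2 and M phase genes (4 of 7 below 0) and -0.10 for epithelial genes (2 of 4). They also turned to -0.022 for leukocyte markers (1 of 2) and -0.047 for interferon-stimulated genes (1 gene). In the other lists reported here they kept the side of the list median. In the DGK family they again rest on DGKZ alone, at 0.16 by its other probe but -0.11 by its main probe. In the mesenchymal list they rest on 1 gene, at 0.17.

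Of 13470 genes measured on both arrays, 26 were at least 2-fold higher with DGKG-CA and 11 at least 2-fold lower, or 19 and 17 after quantile normalization. At 1.5-fold the counts were 303 higher and 165 lower, or 235 and 204 after quantile normalization. Of the 10 highest named genes 3 had spots in patches (H2AB2 at 2.27, MAB21L2 at 1.29, SLC60A1 at 1.21). The others were TPTE2P1 (1.47), FUT3 (1.44), CA9, ANKRD37, COL20A1 (1.22), FLJ33534 (1.19) and the extracellular matrix gene EFEMP2 (1.16, signals 303 and 603). Some of these were dim on the LacZ array, with signals of 40.7 (TPTE2P1), 26.5 (FUT3), 25.4 (COL20A1) and 27.5 (FLJ33534). The lowest signal well above background there was 21.0. The 10 lowest that met the naming rule, which leaves out GINS2, had no spot in a patch and were HERC6 (-1.63), STXBP5L (-1.26), TCF19 (-1.23), CA6 (-1.20), E2F1, SLC6A17 (-1.18), CCNE2, MCM10, the histone gene H2AC13 (-1.01) and CDNF (-0.97). Of genes well above background on 1 array only, CD8B was at least 5.19-fold higher and BNC2 at least 3.95-fold lower, while SLFN14 (at least 13.3-fold higher), DGKB (at least 12.4-fold higher), HOGA1 (at least 3.33-fold lower) and RIPPLY1 (at least 2.84-fold lower) had spots in patches.

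The ratios of DGKG-KD and DGKG-CA to LacZ went together gene by gene. Across the 13329 genes measured on all 3 arrays, 108 were at least 1.5-fold higher on both DGKG arrays (of 184 and 297), 64 were at least 1.5-fold lower on both (of 123 and 164), and 0 lay on opposite sides. Independent lists of these sizes would share 4.10 higher and 1.51 lower genes, and unchanged arrays simulated against 1 shared LacZ array gave 0.060 and 0.14. The correlation across genes was 0.790, against 0.501 simulated, and the covariance 0.0484, against 0.0134 simulated, a difference of 0.0349. Genes are not independent replicates. Both ratios use the same LacZ array, so their lists are not independent even if neither insert acts. That array could not be split, and the simulation gave it the noise of the DGKG-CA to DGKG-KD ratio. Part or all of the excess, and of the shared genes, may therefore come from the LacZ array or its culture. The simulation had a noise SD of 0.116 per array, while spots of probes with signals under 100 had an SD of up to 0.185. Its counts of shared genes are therefore no error rate of these arrays.

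**Figure D3:**
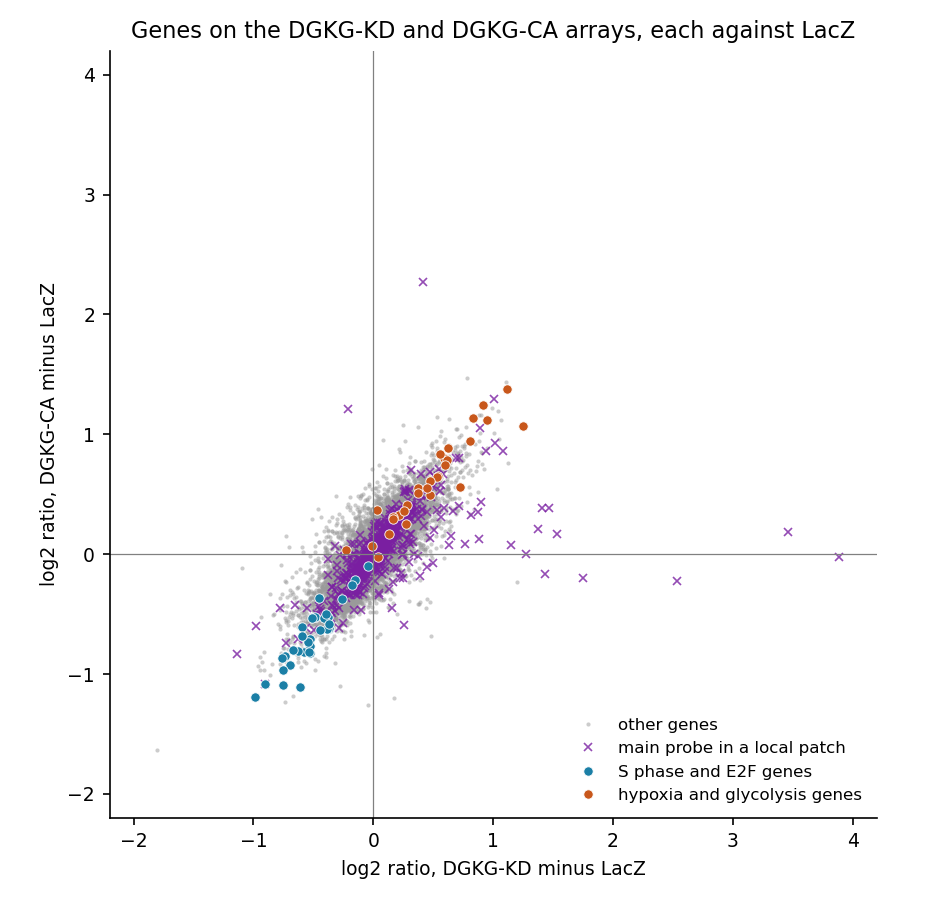
Log2 ratio of DGKG-KD to LacZ (horizontal axis) against that of DGKG-CA to LacZ (vertical axis) for each of 13329 genes well above background on all 3 arrays, 1 array per vector. S phase genes (blue) lie at the lower left and hypoxia genes (orange) at the upper right, and most points spread to the right near 0 on the vertical axis, such as MFHAS1 at 3.88 but not SOX30 at 1.20, have their main probe in a patch (purple crosses).

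Taking each array in turn, without favouring the control, the LacZ array stood apart most often at 1.5-fold but not at 2-fold. At 1.5-fold, 64 genes were higher and 108 lower on the LacZ array than on both others (79 and 88 after quantile normalization, 36 and 32 with normexp), against 15 and 6 for the DGKG-KD array (10 and 0 with normexp) and 13 and 9 for the DGKG-CA array (3 and 0 with normexp). Without spots in patches the counts were 61 and 105 for LacZ, 2 and 6 for DGKG-KD and 13 and 8 for DGKG-CA. At 2-fold, 8 genes stood apart on the LacZ array, 12 on the DGKG-KD array and 4 on the DGKG-CA array, or 7, 1 and 2 without spots in patches. HERC6 was the 1 gene higher on the LacZ array alone (signals 138, 36.9 and 39.4). After quantile normalization 2 genes were higher and 3 lower there. Of 7 genes lower there, the rule named CA9, FUT3, SLC2A3, FLJ33534 and the cytochrome P450 gene CYP4F3. At 2-fold 12 genes were higher on the DGKG-KD array alone, of which 1 was left without spots in patches. On the DGKG-CA array alone H2AB2 and SLC60A1 were higher, both in patches, and STXBP5L and CA6 were lower. The main probe of each had 1 spot, and with the mean of detected probes STXBP5L stood at 0.15 against DGKG-KD, the other side of 0.

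The last comparison set DGKG-CA against DGKG-KD directly. The 2 arrays were closer to each other than either was to LacZ, with an SD of the log2 ratio across genes of 0.165, against 0.233 for DGKG-KD and 0.265 for DGKG-CA relative to LacZ. S phase and E2F genes were lower with DGKG-CA, with a median of -0.18 and 33 of 34 members below 0 (CCNE2 at -0.49, MCM10 at -0.33), and p53 targets too, with a median of -0.13 and 24 of 31 members below 0 (SESN1 at -0.42, MDM2 at -0.40, TP53I3 at -0.39). Hypoxia and glycolysis genes were higher, with a median of 0.13 and 26 of 30 members above 0 (ANKRD37 at 0.33, BNIP3L at 0.33, ALDOC at 0.30), as were G2 and M phase genes, with a median of 0.13 and 35 of 37 members above 0 (CDC25C at 0.39, NEK2 at 0.29, MKI67 at 0.28). All 4 medians lay outside those of all 10000 matched random lists, and no member of these lists was 1.5-fold apart. The medians of members' other probes lay on the same side, but p53 targets were split, at -0.11 with 7 of 12 below 0. They were -0.13 for S phase genes (8 of 8 below 0), 0.16 for hypoxia genes (7 of 7 above) and 0.16 for G2 and M phase genes (5 of 7 above). Relative to the spike-in control probes described below, which shifted by -0.40 here, the S phase and p53 list medians would instead lie above 0.

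Heat shock genes had a median of -0.080 with 16 of 18 below 0 (percentile 0.43, -0.11 to -0.048 under the processing alternatives), but the other probes of 7 members had a median of 0.023, and the medians of the other 14 lists lay between -0.044 for Wnt and beta-catenin targets and 0.063 for NF-kB targets. Of 13402 genes, 2 were at least 2-fold higher with DGKG-CA and 15 at least 2-fold lower, but without spots in patches 0 were higher and 4 lower. At 1.5-fold the counts were 44 and 34 (25 and 42 after quantile normalization, 44 and 19 without spots in patches). The highest named genes were H2AB2 (1.86) and SLC60A1 (1.42), both in patches, then SH3RF2 (0.97), METTL9 (0.88), FOXB1 (0.88), SCARNA10 (0.84) and CRACD (0.83). The main probe of each of these had 1 spot. On the DGKG-KD array the signals were only 30.6 for SH3RF2, 38.3 for METTL9, 34.9 for SCARNA10 and 43.7 for CRACD, against 329 for FOXB1. Of the 10 lowest 7 had spots in patches, from MFHAS1 at -3.91 to C1QTNF5 at -1.27, and the others were SOX30 (-1.43), CA6 (-1.37) and STXBP5L (-1.22, but 0.15 with the mean of detected probes), each with 1 spot for its main probe. The largest bounds, SLFN14 at least 11.3-fold and DGKB at least 10.5-fold higher and KCNK12 at least 23.5-fold, FLJ37201 at least 22.8-fold and ARHGAP25 at least 10.9-fold lower, were in patches, and CD8B, at least 4.40-fold higher, was not.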

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

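The tests of whole-array brightness and of the amount of spike-in mix were chosen after the result was seen. Outside the gene probes, Agilent's spike-in control probes, which detect transcripts named for adenoviral E1A that are added before labelling, were brighter on the DGKG-KD array. Over the 8 of 10 such probes well above background on all arrays, each on 35 spots, the median shift relative to gene probes was 0.649 for DGKG-KD against LacZ (1.57-fold), 0.231 for DGKG-CA against LacZ and -0.40 for DGKG-CA against DGKG-KD. Unscaled, the shift of single probes for DGKG-KD ran from 0.11, for the brightest probe with a signal of 249926 on the LacZ array, to 0.67, for a probe with a signal of 39.5. A DGKG-KD array brighter as a whole is argued against, since the 75th percentile of its gene probes was 0.0909 lower on the log2 scale (-0.0909) than that of the LacZ array. More spike-in mix and less messenger RNA in the labelled sample both predict the same shift of 0.649 and cannot be told apart, because the amounts added are not known here. The shift is larger than the DGKG-KD medians of the hypoxia list (0.47) and the p53 list (0.36), so with the spike-ins as the reference both would lie below the LacZ array, and for DGKG-CA the p53 median (0.21) would too. For DGKG-CA against DGKG-KD the shift (-0.40) is larger in size than the S phase (-0.18) and p53 (-0.13) medians. With the spike-ins as the reference both would lie above the DGKG-KD array. The hypoxia and G2 and M phase medians (both 0.13) would stay above it. No biological explanation was tested, and whether the probes also detect RNA of the vectors was not tested. Control probes named ERCC were well above background on 117, 126 and 105 of 3360 spots on the LacZ, DGKG-KD and DGKG-CA arrays.

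Probes without a gene symbol, which enter none of the counts of genes, also held signals apart from the control. Among those measured on both arrays, 27 of 6047 were at least 2-fold higher and 6 at least 2-fold lower for DGKG-KD against LacZ, and 25 of 6163 were higher and 10 lower for DGKG-CA against LacZ. Between DGKG-CA and DGKG-KD 7 were higher and 15 lower. Spots in patches were not left out of these counts.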

How the results depend on the processing

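The settings without patches and with the GC and signal trend removed were chosen after the data were seen. No paired analysis was possible because each group has 1 array. Counts are given in the order DGKG-KD against LacZ, DGKG-CA against LacZ, DGKG-CA against DGKG-KD, and the cause was not tested unless named. Genes at least 2-fold apart numbered 29, 37 and 17, and 20 of 30 recomputed counts were within 1.5 times of these. They were 7, 8 and 5 with normexp, whose offset draws dim ratios toward 0, 16 and 19 with a signal of at least 100, which tests fewer genes, 548, 773 and 572 with no detection filter, which adds genes at background, and 14 and 4 (first and last comparison) without patches. At 1.5-fold, 311, 468 and 78 genes became 115, 183 and 13 with normexp. Genes with the LacZ, DGKG-KD or DGKG-CA array apart from both others numbered 8, 12 and 4. They were 1, 5 and 0 with normexp, 3, 4 and 0 with a signal of at least 100, and 206, 145 and 222 with no detection filter. For the LacZ array the number was 5 both after quantile normalization and with the trend removed, and without patches 1 was left for DGKG-KD and 2 for DGKG-CA. The correlation of the ratios to LacZ, 0.790, was 0.845 with normexp, 0.771 with the mean of detected probes, 0.861 with a signal of at least 100, 0.589 with no detection filter and 0.822 without patches.

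Of 600 recomputed list medians 562 stayed within their bootstrap spread. The S phase median ran from -0.55 to -0.50 for DGKG-KD and -0.71 to -0.65 for DGKG-CA against LacZ over all settings, the hypoxia median from 0.42 to 0.47 and 0.49 to 0.56, and the p53 median from 0.32 to 0.40 and 0.19 to 0.28. For DGKG-KD against LacZ the medians that moved further were, with no detection filter, 0.27 (DGK family), 0.11 (interferon), 0.082 (NF-kB) and 0.065 (Wnt); with the mean of probes, 0.038 (glycerolipid enzymes), 0.025 (epithelial) and 0.37 (mesenchymal); with quantile normalization, -0.16 (heat shock), 0.015 (ribosomal) and -0.019 (reference). With the trend removed they were -0.098 (G2 and M), 0.058 (ribosomal) and -0.041 (reference), with a signal of at least 100, 0.089 (leukocyte), and for ribosomal genes 0.104 with normexp and 0.112 with median scaling. For DGKG-CA against LacZ they were, with quantile normalization, -0.039 (ERK), -0.18 (heat shock), 0.031 (SRF and YAP) and 0.0034 (ribosomal), and with the trend removed, -0.015 (ERK), 0.094 (unfolded protein response), 0.020 (SRF and YAP) and 0.077 (ribosomal). They were 0.184 (NF-kB) and 0.0091 (Wnt) with no detection filter and 0.108 (ribosomal) with normexp. For DGKG-CA against DGKG-KD they were, with the mean of probes, -0.0067 (interferon), -0.018 (Wnt) and 0.0071 (reference), with normexp, -0.154 (S phase) and -0.014 (Wnt), and with quantile normalization, 0.147 (hypoxia). With a signal of at least 100 they were -0.0067 (interferon) and -0.064 (leukocyte), with no detection filter -0.042 (leukocyte), and with the trend removed -0.017 (leukocyte) and 0.020 (ribosomal).

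Of 2821 recomputed ratios of named genes, 2683 stayed within the spot-to-spot spread, 135 moved further on the same side of 0 or while below 1.5-fold, and 3 turned. C1QTNF5 went to -0.031 (DGKG-KD against LacZ) and 0.035 (DGKG-CA against DGKG-KD) without patches, which left its other spot, and STXBP5L to 0.153 (DGKG-CA against DGKG-KD) with the mean of detected probes. DGKG itself moved to -0.078 for DGKG-CA against DGKG-KD with normexp. The values of the series table and the filter on non-uniform spots moved none of these results past the spread. Those settings had little room to do so. The series table holds the same signal within 0.5%, and non-uniform spots were already left out of the main values. The shares of unmoved results include them. Signals under 100 limit the dim genes, where the spot-to-spot SD of a log2 ratio reached 0.26.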

Other observations

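The gene groups of the next paragraph, the tests on them, and the tests of patch clustering and of culture differences were chosen after the result was seen, as were the settings without patches and with the trend removed. The other tests had their outcome stated beforehand.

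Some groups of genes outside the fixed lists also stood apart from LacZ. Replication-dependent histone genes, which are transcribed in S phase, had a median log2 ratio to LacZ of -0.39 for DGKG-KD (53 of 56 below 0) and -0.336 for DGKG-CA (50 of 57 below 0), with H2AC13 at -0.86 and -1.01 and H2BC7 at -0.92 and -0.96. H2BC12 went the other way at 0.38 and 0.36. A further 35 genes of the G1/S transition and DNA replication had medians of -0.44 and -0.59, with 35 of 35 below 0 on both arrays, among them the phosphatase CDC25A at -0.47 and -0.89, DTL at -0.71 and -0.93 and EXO1 at -0.78 and -0.92. A further set of 29 genes known to be induced by hypoxia, 3 of which stand in another fixed list, had 24 measured members with medians of 0.39 and 0.497, and 21 of 24 above 0 on both arrays. H2AC13, H2BC7 and H2AC4 in the histone set, and RAD51AP1 and TCF19 in the G1/S set, were already seen among the lowest genes when the sets were chosen and remain in them, so these values describe the sets and are no independent test. Between DGKG-CA and DGKG-KD the medians were -0.021, -0.13 and 0.12.

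A hypothesis for the lower S phase and higher hypoxia genes on both DGKG arrays is a property that both DGKG cultures share and the LacZ culture lacks. A trend with probe GC content or signal is argued against as the whole cause. Removing it left at least 91.4% of each of the 4 list medians. Patches are argued against too (at least 96.8% left without them). Quantile normalization left at least 91.9%, which argues only against the choice among scalings on gene probes. It also sets the gene probes of the arrays alike, so it cannot test a shift of them all. With the spike-ins as the reference, the DGKG-KD hypoxia median (0.47) would lie below the LacZ array. The DGKG-CA hypoxia median (0.56) would stay above it, and both S phase medians would lie lower still. Signal of single probes stays open for the hypoxia list, where the other probes of 7 genes had medians of 0.26 and 0.37, as little as 54.4% of the list median, with 6 and 7 of 7 above 0. For the S phase list the other probes had medians of -0.49 (7 of 8 below 0) and -0.69 (8 of 9), close to the list medians of -0.53 and -0.70. Cultures that differed in density, growth stage or viral dose cannot be told apart from an effect of the inserts, because each vector was given to 1 culture, and the interferon-stimulated median of 0.231 for DGKG-CA does not decide it. An effect of DGKG on these genes, and of LacZ on the control culture, stays untested.

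The genes highest on the DGKG-KD array alone may be a surface artifact. Of 172 spots at least 2-fold above both other arrays there, 149 had at least 3 like spots within 3 rows and columns, and the highest of 1000 random placements gave 4. A response of these genes to DGKG-KD is argued against, since 16 spots with copies of the same probes elsewhere on the array showed a median excess of 0.0604 there and at most 0.327. The test covers the probes printed more than once, and genes with 1 spot in a patch, such as MFHAS1, DENND1B and SEC62, have no second reading of that probe.

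HERC6, an interferon-stimulated gene, was lower on both DGKG arrays (-1.81 and -1.63) while 20 of 27 and 19 of 28 genes of its list were above 0. It was read by 1 probe on 1 spot outside any patch, so its ratio has no second reading here. DGKB, another diacylglycerol kinase, read 231 on the DGKG-CA array against 5.30 on the LacZ array at 1 of its 5 probes, on a spot in a patch, and its other 4 probes were not well above background on any array.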
